A study of Mus musculus with 12 samples.

How the data were processed

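Whole-lung RNA from 12 male C57BL/6 mice was sequenced, with 3 mice in each of 4 groups: wild-type (WT) mice on vehicle, WT mice on an agonist of the Mas receptor, Mas-/- mice on vehicle and Mas-/- mice on the agonist. Per the labels' protocols, the lungs were taken at once after death and RNA was extracted with a Qiagen RNeasy kit, and the molecule was total RNA. Groups were taken from the sample titles, which also carry an animal number. No number recurs, so nothing pairs mice across groups. The numbers of all labelled Mas-/- mice and of WT agonist 1 and 2 start with 88, and those of WT agonist 3 and all WT mice on vehicle with 96.

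Per the submitters' processing notes, TopHat2 and Partek were used and the genome build was mm10. The role and version of each tool, the annotation and the strandedness are not given in the sources used here. Without stated strandedness, reads of a gene and of an overlapping antisense gene cannot be told apart. The deposited table holds a value for each of 23064 genes in each of the 12 samples. The file is named for FPKM, but the values deposited by the authors behave as CPM, that is reads scaled to the reads of the whole library, with no division by gene length and with 0.0001 added. The authors do not state this unit, and every level and threshold given in CPM rests on it. In each column most low values, defined as those that round to 20 steps or fewer, lay near whole multiples of a single step, in short and in long genes, and the step was between 0.0265 and 0.0361 across columns. Between 89.9% and 91.1% of these low values lay within 0.1 step of a whole multiple, which is too few to recover whole reads for nearly all genes. The main fit therefore used no count model, and a fit on estimated, rounded reads served only as an alternative. If the step is the value of 1 read, the libraries held 27.7 to 37.7 M reads, of which 20.6 to 27.8 M (median 23.1 M) lay in the listed genes. A level of 1 CPM then rests on 27.7 to 37.7 reads per library, and values near 0.1 CPM rest on a few. The 20 highest genes took 6.74% to 8.52% of the listed reads. Between 21344 and 21978 genes were above 0 in each library. Every pair of replicates within a group differed by more than sampling noise, so all 12 libraries were counted separately.

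Coordinates are those of the deposited table in mm10, given from 1. Gene identifiers were taken from GENCODE vM21 by symbol on the same chromosome, which matched 97.7% of the genes, and 99.4% of the matched genes had the same start in both. For each gene, 1 in 16 of the 31-base words in its annotated transcripts were looked up in transcripts of the other genes of the deposited table. The share found elsewhere is given as shared sequence. Copies in genes outside that table were not searched, so this share may be too low. Genes with a high share are uncertain, because the way the authors' counting treated such reads is not given in the sources used here.

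The tests ran in R 4.3.3 with limma 3.58.1, on log2(CPM + 1) as deposited. Genes with a mean of at least 1 CPM over the 12 samples were tested, which left 15261. A single fit with a mean for each of the 4 groups (8 residual degrees of freedom) gave 7 contrasts: the genotype effect on vehicle, the agonist effect in each genotype, the difference between these agonist effects, the genotype effect on the agonist, and the genotype and agonist effects averaged over the other factor. Spread was moderated with eBayes and a mean trend, p-values are two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(CPM + 1) scale and so understate the change of low genes. The design had assumed FPKM, and the thresholds and the pseudocount were applied to the CPM values without alteration.

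Lists of genes numbered 48 and covered lung cell types, other tissues that a dissected lung can carry, blood cells, pathways tied to Mas and to lung vessels, time of day and handling. The 44 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists within each contrast, and 4 lists had fewer. Members were also adjusted over the list alone. The genes named for a comparison were the 12 called genes with the highest and the 12 with the lowest log2 fold change, or, where under 10 were called, the 6 with the smallest p in each direction. Gene models without an approved symbol were passed over. From each list that passed, the 4 members with the largest change and every called member could be named. Mas1 and the genes Ace, Ace2, Agt, Agtr1a and Mme were always looked at. Agtr2 is not among the genes of the deposited table. These choices were made before the data were examined.

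On simulated data with 50 genes changed at each size in each comparison, over the 15261 tested genes, the fit recovered the following shares in the right direction. In the genotype effect on vehicle these were 24% at a log2 change of 0.5, 84% at 1, 98% at 2 and 100% at 3. For the agonist effect in WT mice they were 54%, 86%, 100% and 98%, for the agonist effect in labelled Mas-/- mice 32%, 90%, 100% and 100%, and for the difference between the agonist effects 14%, 62%, 96% and 100%. Unchanged genes made up 8 of 161, 4 of 173, 9 of 170 and 5 of 141 calls in these comparisons. A simulated list was recovered, with 0 false lists. Genes were simulated as independent of each other, so this does not test camera on lists whose genes vary together.

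The level of Mas1, which is below the filter, was compared with an exact permutation test of 6 against 6 samples. Relations between contrasts that share a vehicle group were set beside 100 simulated draws with no effect. Alternatives were another scaling (median of ratios, quantile), a pseudocount of 0.1, no filter or a mean of at least 5, no trend, array weights, animal number range as a covariate, the compared groups alone, and each library left out in turn. Only the WT agonist group holds both number ranges, so the range covariate is estimated from WT agonist 3 against WT agonist 1 and 2. For the lists, camera with an estimated correlation and fry were run. Added after the data were seen were limma's voom on reads estimated from the step, covariates for heart muscle, fat and airway content, a fit without chromosomes 4 and 17, the range covariate for the lists, and a fit on animal numbers starting with 88 alone. Scripts in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1) prepared the tables, and matplotlib 3.10.9 drew the figures.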

Results

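Whole-lung transcriptomes were measured in 12 male mice aged 200 days after 21 days of treatment. Mas is the receptor for angiotensin-(1-7), the product of the ACE2 branch of the renin-angiotensin system. The design crossed genotype (WT or Mas-/-) with treatment (vehicle or an agonist of Mas), with 3 mice per group. It asks what loss of Mas does to lung expression, what the agonist does, and whether its effect needs Mas. The libraries held 27.7 to 37.7 M reads as estimated from the values. Levels are given in CPM, reads scaled to library size, a unit read from the values and not stated by the authors, as mean ± SD with n = 3 per group unless stated, and log2 fold changes carry their SE from limma.

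Mas1, the targeted gene (chromosome 17, 12841079 to 12868143, mm10), was read first as a check of the labels. It stood at 0.160 ± 0.0991 CPM in the WT libraries and at 0.923 ± 0.212 CPM in those labelled Mas-/- (SD, n = 6 each). The ranges were 0.0311 to 0.291 and 0.640 to 1.24 CPM and did not overlap (exact permutation test, two-sided p = 0.00216, the smallest it can give). Mas1 reads thus went against the genotype label, in 6 of 6 libraries. The deposited value covers the whole gene, which part of it was deleted is not given in the sources used here, and WT levels rest on a few reads. The genotype is therefore written as labelled Mas-/- throughout, and every direction between genotypes rests on the labels. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were present in all libraries, and Xist stayed between 0.421 and 0.931 CPM.

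**Figure D1:**
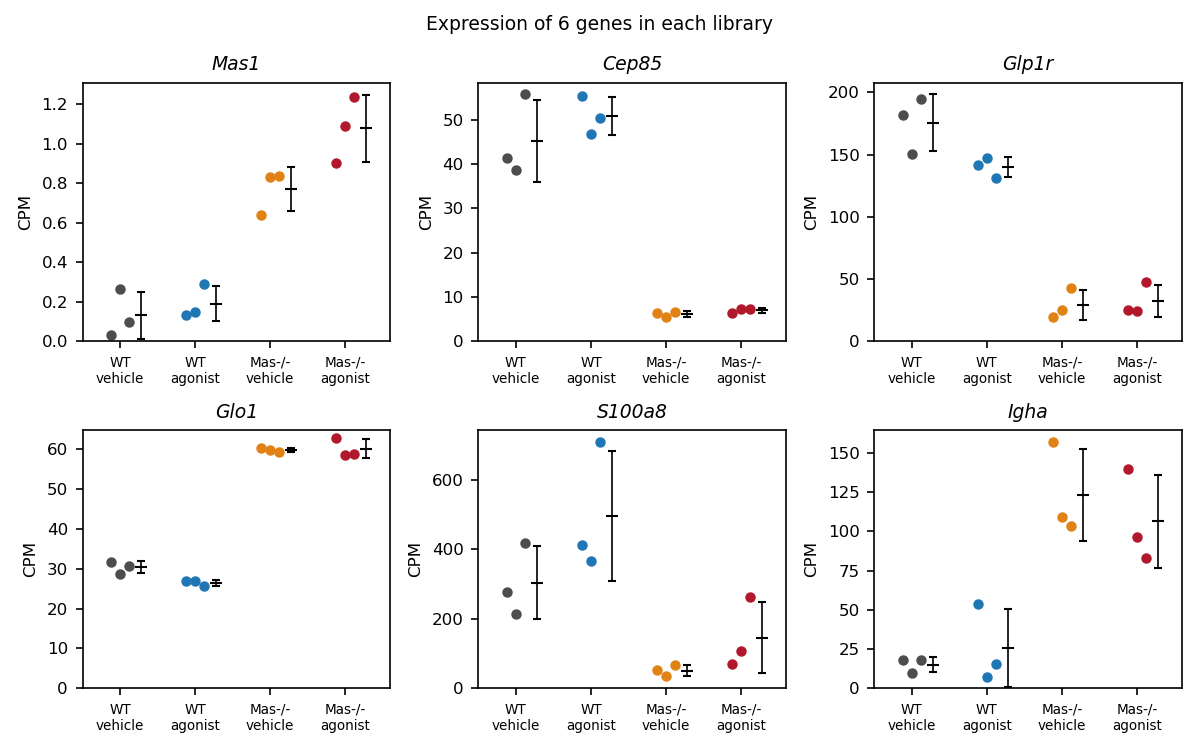
Levels of 6 genes in CPM, chosen for display after their values were seen. Each point is a library, grouped by genotype label and treatment, and the bars give the mean ± SD of the 3 libraries in a group. Mas1 lay at 0.160 CPM in WT libraries and 0.923 CPM in those labelled Mas-/-, and Cep85, Glp1r, Glo1 and Igha did not overlap between labels either. S100a8 did, with 261 CPM in Mas-/- agonist 3 and 214 CPM in WT vehicle 2.

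On vehicle, genes of neutrophils were lower in the lungs labelled Mas-/- than in WT lungs. S100a8, a calcium-binding alarmin abundant in neutrophils, read 303 ± 105 CPM in WT and 50.6 ± 15.7 CPM in labelled Mas-/- lungs (log2 fold change -2.55 ± 0.43, adjusted p = 0.0151). Its partner S100a9 fell by 2.36 on the log2 scale (SE 0.42). Retnlg, a resistin-like protein of granulocytes, went from 83.6 ± 38.6 to 15.9 ± 4.21 CPM, and the chemokine receptor Cxcr2, which guides neutrophils, from 103 ± 35.9 to 29.7 ± 1.63 CPM. Of the 16 tested neutrophil genes, 8 fell when adjusted over all genes, 12 when adjusted over the list alone, and 0 rose. The list median was -1.64 (camera, adjusted p = 1.53e-15). The call is lost with adjusted p = 0.525 with an estimated correlation.

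The gelatinase gene Mmp9, also of the neutrophil list, fell by 1.76 on the log2 scale (SE 0.32). Il1b, which encodes interleukin 1 beta, fell by 1.87 (SE 0.34), while the cytokine list that holds it did not pass on vehicle (camera, adjusted p = 0.0684). Acod1, which makes itaconate in activated macrophages, fell by 2.29 (SE 0.49), and Slfn4 (24.7% shared) went from 89.4 ± 27.6 to 22.8 ± 7.28 CPM. Platelet genes were also lower. The chemokine gene Ppbp (log2 fold change -1.39 ± 0.29) and the collagen receptor gene Gp6 (-0.93 ± 0.20) were called among 13 tested, 12 fell when adjusted over the list alone, and the list median was -0.72 (adjusted p = 3.61e-11, and adjusted p = 0.525 with an estimated correlation).

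Immunoglobulin genes were higher in labelled Mas-/- lungs on vehicle. Igha, the constant region of IgA, rose from 15.1 ± 4.58 to 123 ± 29.3 CPM (log2 fold change 2.96 ± 0.51, adjusted p = 0.0164). Jchain, which joins IgA and IgM subunits, rose from 4.75 ± 2.40 to 32.5 ± 6.75 CPM, and the light-chain gene Igkc by 1.05 on the log2 scale. These were the 3 called of 11 plasma cell genes, and also the 3 adjusted over the list alone (list median 0.33, adjusted p = 0.000437, and adjusted p = 0.639 with an estimated correlation, or 0.17 without Mas-/- vehicle 1 and 0.20 without WT vehicle 1). Cyp1a1, a target of the aryl hydrocarbon receptor, was called higher at 87.6 ± 71.6 against 9.16 ± 2.32 CPM, with a wide spread among the labelled Mas-/- mice.

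The genes with the smallest p on vehicle did not belong to these cell types. Grik3, a kainate receptor subunit gene (chromosome 4, 125490700 to 125714173), stood at 0.105 ± 0.125 CPM in WT lungs and rose by 3.03 (SE 0.13) on the log2 scale. Cep85, a centrosomal protein gene (chromosome 4, 134129858 to 134187112), went from 45.2 ± 9.26 to 6.14 ± 0.606 CPM (log2 fold change -2.68 ± 0.13, adjusted p = 4.68e-07). Hdac1, a histone deacetylase gene (chromosome 4), went from 13.5 ± 0.693 to 1.41 ± 0.265 CPM, and Glp1r, the receptor for glucagon-like peptide 1 (chromosome 17, 30901817 to 30940791), from 176 ± 22.9 to 28.9 ± 12.3 CPM. Chromatin protein genes Hmgn2 (chromosome 4, 29.1% shared) and Hmga1 (chromosome 17, 63.0% shared) fell by 2.16 and by 1.74 on the log2 scale, while Hmga1b (chromosome 11), with 89.7% of its sequence shared with other genes, rose by 1.43. Other called genes with increases were Camk2b, Ces1g, Cd59a, Dnah8, Glo1-ps, Dynlt1b (85.1% shared) and Tmem181b-ps (56.4% shared).

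In all, 205 of 15261 genes were called between genotypes on vehicle, 57 higher and 148 lower in labelled Mas-/- lungs, and 1867 had an unadjusted p under 0.05 where 763 would by chance. Ace, which makes angiotensin II, read 1634 ± 245 CPM in WT and 1327 ± 84.4 CPM in labelled Mas-/- lungs and did not pass (adjusted p = 0.480), nor did Ace2, Agt, Agtr1a or Mme. All 3 WT mice on vehicle have animal numbers starting with 96 and all labelled Mas-/- mice have numbers starting with 88, so number range and genotype cannot be told apart here, and with the range as a covariate 11 genes were called. The count fell to 67 without WT vehicle 3, 74 without WT vehicle 1, 86 and 87 without Mas-/- vehicle 1 and 2, 112 without Mas-/- agonist 2 or WT agonist 1, and 134 without WT agonist 3.

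Further lists passed with camera on vehicle with at most 1 member called, and each lost the call with an estimated correlation (adjusted p = 0.639 or higher with an estimated correlation). Natural killer genes (median 0.32) kept the call within 1.5 times of their median in every removal of a library. Oxidative phosphorylation genes had -0.14 (-0.08 without Mas-/- vehicle 3, -0.09 without WT vehicle 2), general capillary genes -0.22 (-0.13 without WT vehicle 3) and cell cycle genes 0.18 (0.28 without Mas-/- vehicle 2). The other 11 lists lost the call in at least 1 removal. For these, the value given with a removal is the median after it. Extracellular matrix (0.06), ciliated cells (0.04), T cells (0.12) and the neighbours of Mas1 on chromosome 17 (0.08), in which Dynlt1b was called, lost it without Mas-/- vehicle 3. B cells (from -0.30 with all libraries to -0.10) and monocytes and interstitial macrophages (from -0.23 to -0.10) lost it without Mas-/- vehicle 2. So did the circadian clock (0.30) and alveolar type 2 cells (0.11). Chaperones (0.13), alveolar type 2 cells (0.04) and extracellular matrix (0.16) lost it without WT vehicle 1. Ciliated cells lost it also without WT vehicle 3 (0.06) or Mas-/- vehicle 1 (0.22), and monocytes and interstitial macrophages also without WT vehicle 2 (-0.16), WT vehicle 3 (-0.14) or Mas-/- vehicle 1 (-0.18). Adjusted over the list alone, Cd37 and Fcer2a of the B cell list fell and Klrg1 and Prf1 of the natural killer list rose. Of the T cell list Il7r and Lck rose and Trbc2 fell, 2 of 20 capillary genes fell and 3 of 40 Mas1 neighbours rose, again adjusted over the list alone. On vehicle number range and genotype coincide, and the range term comes from WT agonist 3 against WT agonist 1 and 2. The range covariate thus cannot tell range from genotype on vehicle. With the number range as a covariate, 9 of the 18 lists that passed on vehicle passed in the same direction, among them neutrophils (-0.88), platelets (-0.88) and natural killer cells (0.56). Heart muscle genes changed sign with it (from -0.47 to 0.38), and erythroid genes (0.15), T cells (0.03) and plasma cells (0.17) were among the others that did not pass. Heart muscle genes kept the call in 6 of 12 removals of a library, changed sign without Mas-/- vehicle 2 (0.23) or WT vehicle 2 (0.04), and had -0.06 without WT vehicle 1, -1.34 without Mas-/- vehicle 3 and -1.46 without WT vehicle 3. Erythroid genes lost the call without WT vehicle 2 (0.39).

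In WT mice, the agonist was compared with vehicle under the WT label. Genes of the mesothelium, the cell layer that covers the lung, had higher levels on the agonist, although no single gene passed over all genes. Msln, which encodes mesothelin, read 19.7 ± 12.8 CPM on vehicle and had a log2 fold change of 1.48 ± 0.36 on the agonist, and Muc16, a surface mucin gene, read 4.44 ± 2.01 and 15.6 ± 6.37 CPM. The transcription factor gene Wt1 read 0.630 ± 0.0750 and 2.20 ± 0.585 CPM, and Ildr2 read 5.78 ± 1.69 and 13.8 ± 1.06 CPM. Of 15 mesothelial genes, 0 were called over all genes and 8 rose when adjusted over the list alone (list median 0.65, camera adjusted p = 7.28e-11). The list call is lost with adjusted p = 0.433 with an estimated correlation.

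Several further cell type lists differed with the agonist in WT mice. Neutrophil genes had a median of 0.64 (0.37 without WT agonist 3, adjusted p = 7.31e-08, and adjusted p = 0.445 with an estimated correlation) with 16 of 16 genes above 0, among them Camp, an antimicrobial peptide gene, at 1.23 ± 1.78 and 4.79 ± 1.27 CPM. T cell genes had a median of 0.21 (adjusted p = 0.433 with an estimated correlation) and 4 rose when adjusted over the list alone, led by Il7r, the interleukin 7 receptor gene, at 13.6 ± 1.25 and 21.9 ± 3.65 CPM. Ciliated cell genes had a median of -0.39 (-0.18 without WT agonist 1, -0.61 without WT vehicle 3, adjusted p = 0.445 with an estimated correlation), with Tekt1, a component of cilia, at 10.8 ± 0.542 and 6.74 ± 1.81 CPM. Oxidative phosphorylation genes differed little each, with 34 of 40 below 0 and a median of -0.17 (adjusted p = 1.48e-10, and adjusted p = 0.433 with an estimated correlation). Heart muscle genes, which a lung sample carries in vein walls or attached tissue, had a median of -1.36 (adjusted p = 0.459 with an estimated correlation), which was -0.84 without WT vehicle 1 or WT agonist 1 and -2.34 without WT vehicle 3, with Myh6 at 478 ± 364 and 116 ± 72.6 CPM. None of the members of these lists passed over all genes.

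In this comparison limma called 0 of 15261 genes, with 846 at an unadjusted p under 0.05 (763 by chance) and 0 by voom. The smallest adjusted p was 0.185, for a gene of the mesothelial list, Ildr2. Next in order of p came Il7r, Scel, Sla, Wt1 and Pkhd1l1 with higher and Mgst3, Chchd10, Cxcl12, Hhatl, Lrrc23 and Igfbp3 with lower levels on the agonist, each at an adjusted p of 0.866. Igfbp3, an insulin-like growth factor binding protein gene, read 99.4 ± 7.26 CPM on vehicle and 67.4 ± 15.4 CPM on the agonist. A total of 25 lists passed with camera and 0 with an estimated correlation or with fry. Array weights gave 12 calls, and leaving out Mas-/- vehicle 2 or WT agonist 3 gave 1. WT mice on vehicle all have animal numbers starting with 96, while WT agonist 1 and 2 have numbers starting with 88, so the agonist effect in WT mice is largely confounded with number range. With the range as a covariate this effect is WT agonist 3 alone set against WT vehicle. Values from that setting rest on 1 treated mouse and cannot show that an effect is free of the range. With the range as a covariate the smallest adjusted p was 0.770, where all settings ranged from 1.82e-06 (without WT agonist 3) to 0.806 (without WT agonist 1), and 605 genes had an unadjusted p under 0.05. With that covariate mesothelial genes had a median of 0.62 and oxidative phosphorylation genes -0.20. Interferon-stimulated genes turned from above to below 0 (-0.04), and erythroid (0.26) and club cell genes (-0.04) lost the call.

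Of the remaining 19 lists that passed in WT mice, smooth muscle genes (median -0.47) kept the call within 1.5 times of their median in every removal of a library. Monocyte and interstitial macrophage genes had 0.28 (0.18 without WT vehicle 1), natural killer genes 0.23 (0.37 without WT agonist 2) and glucocorticoid response genes 0.27 (0.12 and 0.45 without WT agonist 1 and 2). The other lists lost the call in at least 1 removal. Without WT vehicle 1, it was lost by alveolar type 2 cells (from 0.17 to 0.03), alveolar macrophages (0.21 to 0.09), cytokines (0.28 to 0.20), fatty acid oxidation (-0.15 to -0.05) and actin and Rho signalling (0.07 to 0.04). Without WT vehicle 3, alveolar type 2 cells had 0.26, cytokines 0.42 and fatty acid oxidation -0.28. Erythroid genes (0.81, or 1.36 without WT vehicle 3) lost the call without WT vehicle 2 (0.21) or WT agonist 2 (0.35). Immediate early genes (0.39, or 0.25 without WT vehicle 3) lost it without WT agonist 3 (0.21), and club cell genes (-0.41, or -0.26 without WT vehicle 2) without WT agonist 1 (-0.19). Interferon-stimulated genes, BMP and TGF-beta signalling, B cells, skeletal muscle, platelets, adipocytes and general capillary endothelium lost it in 2 or more removals, and without WT vehicle 3 platelet genes (0.06) and general capillary genes (0.02) changed sign. With an estimated correlation each of the 19 lists was at adjusted p = 0.433 or higher. Adjusted over the list alone, Prf1 of the natural killer list rose and Cxcl12 of the cytokine list fell.

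In labelled Mas-/- mice, the agonist was compared with vehicle to ask what it does under the Mas-/- label. Erythroid genes had lower levels on the agonist. The globin gene Hbb-bs read 610 ± 220 CPM on vehicle and 204 ± 54.5 CPM on the agonist, and Alas2, the first enzyme of heme synthesis in red cells, 30.4 ± 3.46 and 9.12 ± 3.12 CPM. Of 9 erythroid genes, 0 were called over all genes and 7 fell when adjusted over the list alone (list median -1.52, adjusted p = 1.70e-10, and adjusted p = 0.7505 with an estimated correlation). Neutrophil genes had a median of 0.52 with 16 of 16 above 0, among them S100a8 at 50.6 ± 15.7 and 146 ± 101 CPM (adjusted p = 6.65e-06 for the list, and adjusted p = 0.900 with an estimated correlation). This rested on Mas-/- agonist 3, where S100a8 read 261 CPM against 70.5 and 106 CPM in the other agonist libraries. Without Mas-/- agonist 3 the list lost the call (median 0.38), and the difference in neutrophil score went from 0.61 to 0.19. Without Mas-/- vehicle 3 or Mas-/- agonist 1 the median was 0.89 and 0.86.

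The other 6 lists that passed in labelled Mas-/- mice were adipocytes (median -1.09), fatty acid oxidation (-0.14), oxidative stress response (-0.12), extracellular matrix (-0.11), heart muscle (-0.60) and cytosolic ribosomal proteins (0.13), each at adjusted p = 0.900 with an estimated correlation. Adipocyte genes were highest in 1 library. Cfd read 56.2 ± 90.5 CPM on vehicle and 7.40 ± 8.57 CPM on the agonist, and Mas-/- vehicle 3 had an adipocyte score of 3.24 against 0.85 for the next highest library. Without Mas-/- vehicle 3 the medians of adipocytes (0.30), heart muscle (0.19) and ribosomal proteins (-0.03) changed sign, and these lists, fatty acid oxidation (-0.03) and extracellular matrix (-0.01) lost the call. Without Mas-/- agonist 2, heart muscle (-0.09), ribosomal proteins (0.07) and extracellular matrix (-0.07) lost it, and adipocytes had -0.60. Oxidative stress response changed sign and lost the call without Mas-/- vehicle 1 (0.01), where extracellular matrix had -0.16 and ribosomal proteins 0.24, the latter with 0.21 without Mas-/- agonist 3. Without Mas-/- vehicle 2 the medians of adipocytes (-1.98), heart muscle (-1.28), fatty acid oxidation (-0.21) and oxidative stress response (-0.19) lay further from 0. Limma called 0 genes, with 531 at an unadjusted p under 0.05 and 0 by voom, and 2 were called without Mas-/- vehicle 2. Cyp1a1 had 87.6 ± 71.6 CPM on vehicle and 13.5 ± 3.75 CPM on the agonist (log2 fold change -2.35 ± 0.43, adjusted p = 0.982). Entpd4 (100% shared), Rasd2, Syt7, Sh2b2 and Ces1g came next among lower and Yy2 (100% shared), Aopep, Cntn1, Wsb1, Lhfpl4 and Tmem254b (100% shared) among higher genes, none past the threshold.

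**Figure D2:**
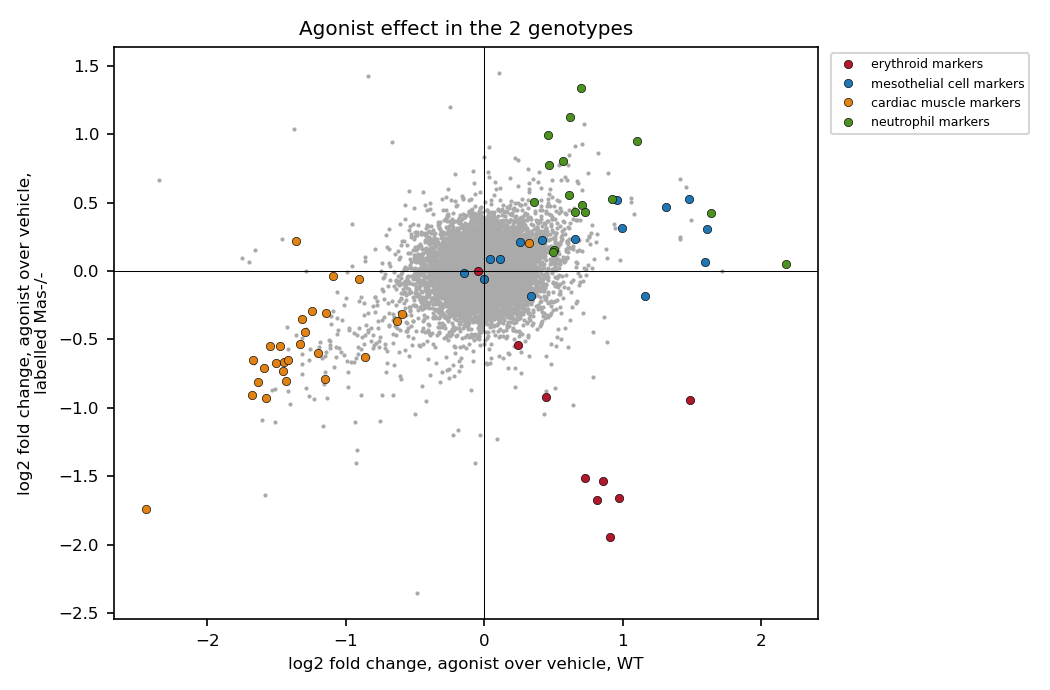
Log2 fold change of the agonist over vehicle in WT mice (horizontal axis) against that in mice labelled Mas-/- (vertical axis), a point per tested gene. Coloured points are genes of the erythroid, mesothelial, heart muscle and neutrophil lists. Erythroid genes lay mostly to the right and below 0, and neutrophil genes lay above 0 in both (16 of 16 each).

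Whether the agonist acted differently in the 2 genotypes was tested as the difference between its effects. Erythroid genes differed most, with a median difference of -2.40 (adjusted p = 4.42e-11, and adjusted p = 0.332 with an estimated correlation), and 8 of 9 passed as lower when adjusted over the list alone. Hba-a1, a globin gene, had 144 ± 136 and 230 ± 135 CPM in WT mice on vehicle and agonist, and 286 ± 100 and 89.5 ± 31.3 CPM in labelled Mas-/- mice. Ildr2 had a difference of -1.34 ± 0.23 and Igfbp3, which read 114 ± 17.3 and 147 ± 10.9 CPM in labelled Mas-/- mice, one of 0.95 ± 0.21. Sh2b2, an adaptor gene of receptor signalling, had the smallest p, with a difference of -1.06 ± 0.18 (adjusted p = 0.631). Limma called 0 genes, with 632 at an unadjusted p under 0.05 and 0 by voom. A total of 19 lists passed with camera and 0 with an estimated correlation (smallest adjusted p = 0.332 with an estimated correlation). Erythroid genes and oxidative phosphorylation were the 2 that kept the call within 1.5 times of their median in every removal of a library. The WT part of this difference is confounded with animal number range. With the range as a covariate that part is WT agonist 3 alone set against WT vehicle, and the erythroid median was -1.88.

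Between genotypes on the agonist, neutrophil genes were again lower under the Mas-/- label. S100a8 read 495 ± 186 CPM in WT and 146 ± 101 CPM in labelled Mas-/- lungs (log2 fold change -1.91 ± 0.43), and Il1r2, a decoy receptor for interleukin 1, 31.1 ± 12.6 and 8.54 ± 4.39 CPM. The protease gene Asprv1 went from 22.0 ± 7.58 to 4.44 ± 1.06 CPM. Of the 16 neutrophil genes, 8 fell over all genes and 15 when adjusted over the list alone (median -1.67, adjusted p = 2.44e-18, and adjusted p = 0.364 with an estimated correlation). Monocyte and macrophage genes had a median of -0.44, with the receptor genes Cd14 (55.7 ± 12.7 and 28.4 ± 4.63 CPM) and Fcgr4 (16.4 ± 0.525 and 7.56 ± 3.23 CPM) called among 18 and 10 lower when adjusted over the list alone (adjusted p = 5.69e-09, and adjusted p = 0.364 with an estimated correlation). The antiviral genes Oas3 and Oasl2 fell by 1.51 and by 0.69 on the log2 scale.

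Higher in labelled Mas-/- lungs on the agonist were immunoglobulin and ciliated cell genes. Igha read 25.5 ± 24.8 CPM in WT and 106 ± 29.6 CPM in labelled Mas-/- lungs, and Igkc and Mzb1, a chaperone gene of antibody-secreting cells, were also called (3 of 11 over all genes, 4 when adjusted over the list alone, median 0.51, or 0.27 without Mas-/- agonist 3, adjusted p = 0.506 with an estimated correlation). Ciliated cell genes had a median of 0.57 (0.36 without WT agonist 1), with Tekt4 called at 5.98 ± 1.49 and 11.1 ± 0.938 CPM and 5 of 24 higher when adjusted over the list alone (adjusted p = 9.46e-10, and adjusted p = 0.506 with an estimated correlation). Glo1, which detoxifies methylglyoxal (chromosome 17, 30584936 to 30626871), rose from 26.5 ± 0.792 to 60.2 ± 2.41 CPM, and the potassium channel regulator gene Kcnrg by 1.16 on the log2 scale. Grik3, Cep85, Hdac1, Glp1r, Hmgn2 and Hmga1 were called again in the direction seen on vehicle, and Vmn2r97, Stfa2l1 and Dynlt1-ps1 (100% shared) were among the genes with the largest changes.

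In total 281 genes were called between genotypes on the agonist, 56 higher and 225 lower, with 2003 at an unadjusted p under 0.05. Of these, 138 were also called on vehicle, all in the same direction (29 higher and 109 lower, where independent lists would share 0.209 and 2.18). The comparisons share no library, but they share each gene's estimate of spread, so independence may be too low a baseline. The count of genes called on the agonist was 49 without WT agonist 3, 57 and 62 without Mas-/- agonist 1 and 2, 93 without WT agonist 1, 176 without WT vehicle 1 and 424 without Mas-/- vehicle 3. Among animals with numbers starting with 88 alone, 63 genes were called, of which 60 were among the 281. With the number range as a covariate 14 of the 18 lists that passed on the agonist passed in the same direction, neutrophils among them.

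The other lists that passed between genotypes on the agonist had no more than 5 members past the threshold over the list alone. Platelets (median -0.43), cytokines (-0.23, Il1b called, 5 adjusted over the list alone) and glycolysis and hypoxia (-0.15) kept the call within 1.5 times of their median in every removal of a library. Erythroid genes had -1.23 (-0.81 without WT agonist 2), and 5 of 9 were lower adjusted over the list alone. Club cell genes had 0.45 and lost the call without Mas-/- agonist 1 (0.19) or WT agonist 1 (0.25). Chaperones (0.18, or 0.31 without Mas-/- agonist 3) lost it without Mas-/- agonist 2 (0.15) or WT agonist 1 (0.10), and mesothelium (-0.36) without WT agonist 1 (-0.19), WT agonist 3 (-0.29) or Mas-/- agonist 3 (-0.37). Alveolar macrophages (-0.18) lost it without Mas-/- agonist 1 (-0.22) or WT agonist 2 (-0.21). Immediate early genes, interferon-stimulated genes, BMP and TGF-beta signalling, cell cycle, general capillary endothelium and arterial, venous and lymphatic endothelium also passed and lost the call in at least 1 removal. Each had adjusted p = 0.381 or higher with an estimated correlation. Cell cycle kept the call in 3 of 12 removals of a library and changed sign without Mas-/- agonist 1 (-0.05). Interferon-stimulated genes changed sign and lost the call without Mas-/- agonist 3 (0.03) or WT agonist 1 (0.01), as did immediate early genes without Mas-/- agonist 3 (0.00).

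Averaged over treatments, 693 genes were called between genotypes, 168 higher and 525 lower in labelled Mas-/- lungs, with 2797 at an unadjusted p under 0.05. Neutrophil genes fell in 12 of 16 cases over all genes and 15 when adjusted over the list alone (median -1.65, adjusted p = 5.24e-20). This was the single list that passed with fry (adjusted p = 0.0171), and it had adjusted p = 0.453 with an estimated correlation. Platelet genes fell in 4 of 13 cases, 12 when adjusted over the list alone (median -0.57, adjusted p = 0.453 with an estimated correlation). Monocyte and macrophage genes fell in 2 of 18 cases, 9 when adjusted over the list alone (median -0.29, adjusted p = 0.453 with an estimated correlation). Cytokine genes fell in 4 of 21 cases, among them Cxcl2, a neutrophil attractant (log2 fold change -1.17 ± 0.25), and Lcn2 (-1.11 ± 0.25), and 6 fell when adjusted over the list alone (adjusted p = 0.453 with an estimated correlation). Plasma cell genes rose in 4 of 11 cases, also 4 adjusted over the list alone (median 0.42, adjusted p = 0.542 with an estimated correlation).

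Wfdc17, Mmp8, Erdr1 and Ifitm6 joined the genes with the largest decreases in the average. Mmp8, a neutrophil collagenase gene, read 46.9 ± 19.3 CPM in WT and 13.7 ± 8.21 CPM in labelled Mas-/- lungs on vehicle, and 91.2 ± 42.3 and 24.6 ± 23.7 CPM on the agonist. Ciliated cell genes had a median of 0.41 (adjusted p = 0.744 with an estimated correlation), lay above 0 in 24 of 24 cases, and 1 rose both over all genes and adjusted over the list alone. Further lists that passed, with members called over all genes and then adjusted over the list alone, were chaperones (0.20, 1 and 4 higher), general capillary endothelium (-0.18, or -0.11 without WT vehicle 3, 0 and 7 lower) and glycolysis and hypoxia (-0.10, 2 and 4 lower). The next 5 lists lost the call in at least 1 removal of a library. Club cells (0.29, 2 and 2 higher) lost it without Mas-/- vehicle 3 (0.22), WT vehicle 3 (0.21) or WT agonist 1 (0.22), and their mean over genes went from 0.37 to 0.07, 0.14 and 0.21. Cell cycle (0.15, 1 and 2 higher) lost it without Mas-/- agonist 1 (0.06), and B cells (-0.16, 1 and 1 lower) without Mas-/- vehicle 2 (-0.06), WT vehicle 1 (-0.05), Mas-/- agonist 3 or WT agonist 1 (-0.12 each). Arterial, venous and lymphatic endothelium (-0.14, or -0.22 without Mas-/- vehicle 3) lost it without Mas-/- vehicle 1 (-0.16) and had 0 called and, adjusted over the list alone, 1 higher and 6 lower. The neighbours of Mas1 (5 and 6 higher) lost it in 4 removals. All of these had adjusted p = 0.554 or higher with an estimated correlation. The count of called genes was 422 and 438 without Mas-/- agonist 1 and 2, 435 without WT agonist 3 and 1123 without Mas-/- vehicle 3, and 33 with animal number range as a covariate, with which 11 of the 14 lists passed in the same direction.

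Called genes lay unevenly along the genome. On chromosome 17 between 5 and 60 Mb, the stretch that holds Mas1, 92 of 622 tested genes were called in the average, 28 higher and 64 lower in labelled Mas-/- lungs. On chromosome 4 between 110 and 150 Mb, 58 of 427 were called, 5 higher and 53 lower. Elsewhere 543 of 14212 were called, 135 higher and 408 lower, so calls were mostly lower outside the stretches too. The bounds of the stretches were chosen after the calls were seen. In windows of 5 Mb over the whole genome, 28 of 81 genes were called at 20 to 25 Mb on chromosome 17 and 28 of 84 at 130 to 135 Mb on chromosome 4, and 16 was the highest count in any window when the calls were permuted over genes.

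**Figure D3:**
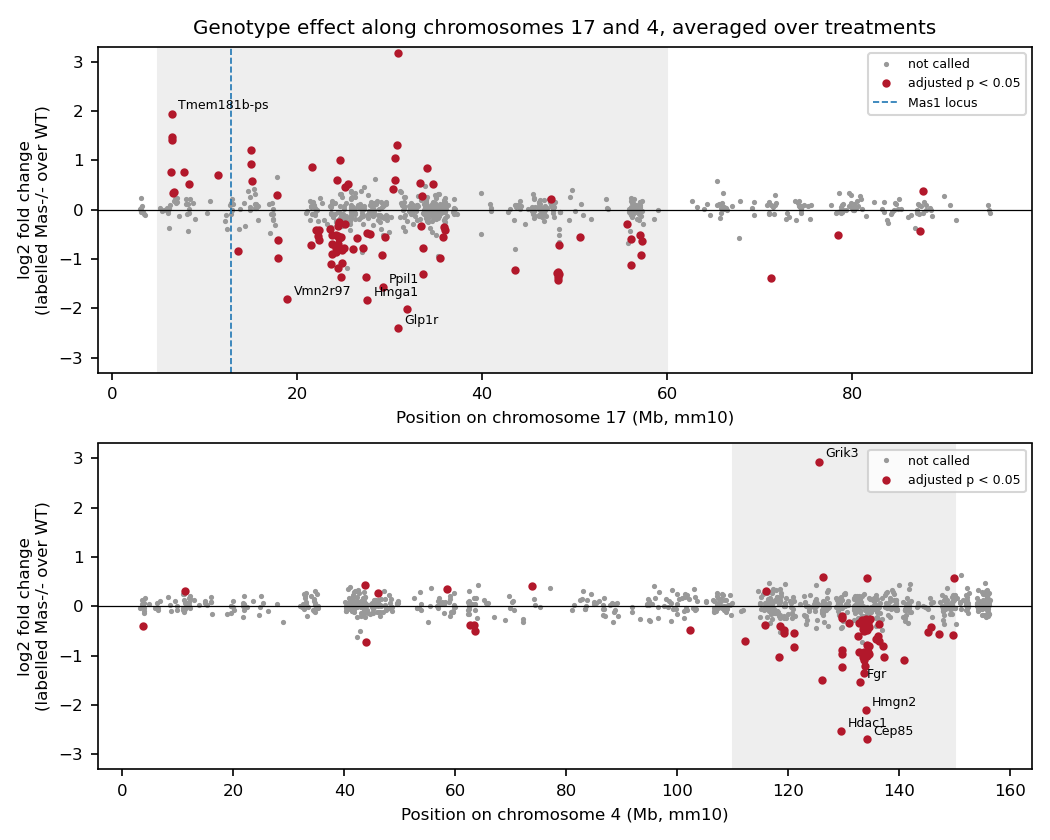
Log2 fold change between genotypes, labelled Mas-/- over WT, averaged over treatments, against gene position in Mb (mm10) on chromosomes 17 and 4. Red points are called genes, grey points other tested genes, the grey bands the stretches of 5 to 60 Mb and 110 to 150 Mb, and the dashed line the Mas1 locus. The bands were drawn after the calls were seen, and on chromosome 4 the called genes within them are mostly lower (53 of 58). Outside the bands, over the whole genome, called genes are mostly lower too (408 of 543).

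Averaged over genotypes, the agonist raised or lowered no single gene past the threshold. Limma called 0 of 15261 genes, with 765 at an unadjusted p under 0.05, which is close to the 763 expected, and 0 by voom, while 1 was called with array weights or without WT agonist 3 and 2 without Mas-/- vehicle 2. Neutrophil genes lay above 0 in 16 of 16 cases (median 0.65, adjusted p = 1.40e-11, and adjusted p = 0.545 with an estimated correlation), 8 rose when adjusted over the list alone, and S100a8 had a log2 fold change of 1.02 ± 0.30. Mesothelial genes had a median of 0.44 (adjusted p = 1.62e-09, and adjusted p = 0.545 with an estimated correlation), and 8 rose when adjusted over the list alone, among them Upk3b (0.89 ± 0.23). Heart muscle genes had a median of -0.97 (adjusted p = 3.42e-10, and adjusted p = 0.545 with an estimated correlation), or -0.58 without Mas-/- vehicle 3 and -1.46 without WT vehicle 3, with 0 past the threshold over the list alone. Sla, Wt1, Lilra5, Il7r, Yy2 and Ildr2 had the smallest p among higher and Syt7, Cyp1a1, Mgst3, Grin2d, Chchd10 and Reep6 among lower genes, each at an adjusted p of 0.920.

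Another 15 lists passed for the averaged agonist effect. Each moved by over 1.5 times or lost the call in at least 1 removal of a library. Without Mas-/- vehicle 3, the median went from -0.82 to -0.23 for adipocytes, from -0.27 to -0.10 for club cells, from -0.29 to -0.11 for smooth muscle and from 0.21 to 0.12 for immediate early genes, and glucocorticoid response lost the call (0.18 to 0.12). Without Mas-/- vehicle 2 it was -1.36 for adipocytes, -0.47 for club cells, -0.30 for ciliated cells (-0.19 with all libraries) and 0.08 for T cells (0.14). Without WT agonist 1 it was -0.08 for ciliated cells, -0.16 for club cells and 0.09 for T cells, and without WT agonist 3 it was 0.12 for immediate early genes. Fatty acid oxidation genes had -0.11 (-0.06 without WT vehicle 1, -0.19 without WT vehicle 3) and oxidative phosphorylation genes -0.07 (-0.04 without Mas-/- vehicle 1, -0.05 without WT vehicle 2). Monocyte and interstitial macrophage genes had 0.14 (0.09 without Mas-/- agonist 3) and lost the call without WT vehicle 1 (0.08). Cytokines, skeletal muscle, oxidative stress response, erythroid genes and interferon-stimulated genes lost it in 3 or more removals. Each had adjusted p = 0.545 or higher with an estimated correlation. Il7r of the T cell list rose when adjusted over the list alone. With the number range as a covariate the WT part of the averaged agonist effect rests on WT agonist 3 alone, so that setting cannot free these lists of the range.

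**Figure D4:**
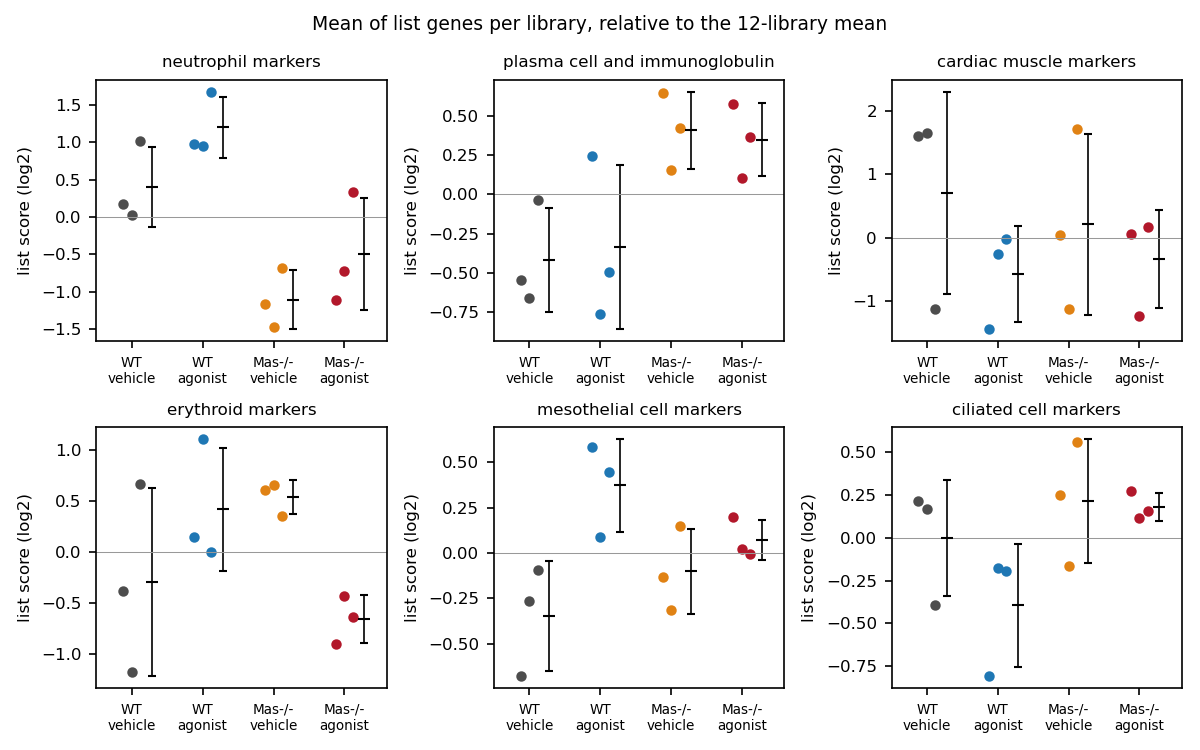
Score of 6 gene lists per library, the mean of the genes' log2(CPM + 1) relative to the mean of all 12 libraries, by genotype label and treatment. Points are libraries and bars the mean ± SD of 3. Neutrophil scores were lower and plasma cell scores higher in most labelled Mas-/- libraries, and heart muscle scores went from -1.13 to 1.71 among the labelled Mas-/- vehicle libraries.

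Some libraries stood apart. The first principal component held 33.4% of the variance and placed Mas-/- vehicle 3 at -43.8, while all others lay between -14.8 and 25.2. That library also had the highest scores for adipocytes (3.24), heart muscle (1.71), club cells (1.41) and ciliated cells (0.56). WT vehicle 1 and 2 had heart muscle scores of 1.59 and 1.65 and WT vehicle 3 one of -1.13. The second component held 25.8% of the variance and split the labelled Mas-/- libraries across both treatments. Mas-/- vehicle 1 and 2 and Mas-/- agonist 1 and 2 lay between 17.78 and 25.12. Mas-/- vehicle 3 (-8.28) and Mas-/- agonist 3 (-0.65) lay nearer the WT libraries (-20.01 to -8.61). Circadian clock scores split them likewise, at 0.288 to 0.385 against -0.199 and -0.373. The source of this split was not tested.

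The agonist effects in WT and labelled Mas-/- mice, which share no library, were weakly related across genes (Pearson 0.24, Spearman 0.07), where simulated groups without an effect ranged from -0.66 to 0.77. Genes are not independent replicates, so no p is given. The genotype effect on vehicle and the agonist effect in WT mice share the WT vehicle group and had a Pearson correlation of 0.08, where 100 simulated draws without an effect averaged 0.49, and a covariance of 0.00461 against 0.0214. The genotype effect on vehicle and the agonist effect in labelled Mas-/- mice share the labelled Mas-/- vehicle group and had -0.46 against a simulated -0.47, and a covariance of -0.0223 against -0.0197. Both differences between observed and simulated covariance were below the spread of the simulated values (SD 0.0176). The vehicle groups, with 3 libraries each, were too small to split.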

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

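The following lists were flagged because the agonist effect differed between genotypes at an adjusted p under 0.05 with camera at the preset correlation, and 0 of them passed with an estimated correlation. Values are the median over genes of the agonist's log2 fold change in labelled Mas-/- mice minus that in WT mice. Erythroid genes had -2.40 (0.81 in WT, -1.52 in labelled Mas-/- mice, adjusted p = 4.42e-11, and adjusted p = 0.332 with an estimated correlation), mesothelial genes -0.44, natural killer genes -0.27, monocyte and interstitial macrophage genes -0.26, alveolar macrophage genes -0.25, T cell genes -0.22, alveolar type 2 genes -0.21 and immediate early genes -0.19. Oxidative stress response had -0.13, BMP and TGF-beta signalling -0.13 and extracellular matrix -0.10. Above 0 were cytosolic ribosomal proteins at 0.13, oxidative phosphorylation at 0.20, aerocyte endothelium at 0.21, B cells at 0.23, platelets at 0.26, ciliated cells at 0.29, smooth muscle at 0.34 and heart muscle at 0.80. Adjusted over the list alone, 8 erythroid, 2 natural killer, 1 mesothelial and 1 BMP and TGF-beta gene passed, all lower. On leaving out 1 library, erythroid genes and oxidative phosphorylation kept the call within 1.5 times of their median, 11 of the 19 lists lost it at least once and 3 changed sign, namely ribosomal proteins (-0.06) and extracellular matrix (0.02) without Mas-/- vehicle 3 and oxidative stress response (0.03) without Mas-/- vehicle 1. Heart muscle went from 0.01 (without Mas-/- vehicle 2) to 1.81 (without WT vehicle 3). Limma called 0 single genes for this difference.

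Of the tests on the genotype calls of chromosomes 4 and 17, all but that of the copies themselves were chosen only after the result was seen. The highest count of called genes in a 5 Mb window was 28, on chromosome 17 and on chromosome 4, and 16 was the highest in 1000 permutations, which argues against chance placement and, by the same count, against Mas loss acting on genes wherever they lie as the cause of the concentration. Of the 117 genes called lower in the stretches, 108 fell by more than the loss of every read in their shared sequence allows. For these genes this argues against reads moved to copies among the genes of the deposited table. A gene with almost no shared sequence meets this bound by being called lower. Copies outside that table were not searched, so reads moved to them stay open. The copies outside the stretches number 4, have a median log2 fold change of -0.00781 and spread from -0.10 to 1.29 (Hmga1b), too few to decide for the genes they copy. The permutations place each gene alone, so an effect of Mas loss on neighbouring genes regulated together stays open. Another strain's genome carried along with the Mas1 locus stays open for chromosome 17 alone, and for the unlinked chromosome 4, with 58 called genes, a separate stretch of other background stays open, neither testable without reads.

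For lower neutrophil genes under the Mas-/- label, the tests of blood, myeloid content and number range on vehicle were chosen only after the result was seen, as was the fit on animal numbers starting with 88. On vehicle erythroid genes had a median of 1.02 (0.39 without WT vehicle 2, 1.57 without WT vehicle 3, 0.15 with the range covariate) while neutrophil genes had -1.64. Erythroid genes thus showed no fall there. Their scores overlapped between mice, from -1.17 to 0.67 in WT and from 0.35 to 0.66 in labelled Mas-/- libraries, so less blood is not decided on vehicle. On the agonist erythroid genes had -1.23 (-0.81 without WT agonist 2), T cell genes -0.04, B cell genes 0.08 and platelet genes -0.43, so less blood stays open there. The alveolar macrophage list had -0.0722 (SD over genes 0.31) in the average, which argues against a lower share of all myeloid cells, but monocytes and interstitial macrophages had -0.29 and platelets -0.57, so fewer recruited blood cells of several types stay open. Among agonist mice with numbers starting with 88, 2 WT and 3 labelled Mas-/-, the neutrophil median was -1.42, which argues against the range as the cause on the agonist, while on vehicle it was -0.880 with the range as a covariate and range and genotype cannot be told apart.

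For lower oxidative phosphorylation genes with the agonist in WT mice, the heart muscle covariate was chosen only after the data were seen. With heart muscle content as a covariate the median was -0.141, which is 84.9% of the value without it and argues against heart tissue as the whole cause. Without WT vehicle 2 it was -0.117, or 70.5%, so a part played by 1 library stays open.

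Libraries were also regrouped at random, with tests written before the result was seen. Between genotypes averaged over treatments, the real grouping gave 693 calls and the highest other 135. Of 100 splits 1 reached the real count, the real grouping itself. This is the smallest share these splits can give, and it argues against chance as the source of the count without excluding it. Between genotypes on the agonist the real grouping gave 281 and the highest other 0 (1 of 10 splits reached it), and on vehicle 205 and 198 (1 of 10). The split with 198 set Mas-/- vehicle 1 and 2 and WT vehicle 3, with heart muscle scores of 0.04, -1.13 and -1.13, against libraries with scores of 1.59 to 1.71. The agonist comparisons within WT and within labelled Mas-/- mice each gave 0, with 0 as the highest other (10 of 10). In these 4 comparisons 10 splits are too few for a share under 0.05. For the difference between agonist effects the real count was 0 and the highest other 0 (100 of 100), and for the averaged agonist effect 0 and 1 (100 of 100). Every split reaches a count of 0, so these splits decide nothing.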

How the results depend on the processing

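With 3 mice per group, counts of called genes moved widely with the setting, while 0 called genes changed sign; where a count moved, the cause was not tested. Between genotypes on vehicle (205 calls) the count was 373 with array weights, 11 with animal number range as a covariate, 51 with only the groups compared, and, in settings added after the data were seen, 132 with voom, 381 with a heart muscle covariate and 30 without chromosomes 4 and 17. Leaving out a library gave 67 (WT vehicle 3) to 232 (Mas-/- vehicle 3), with 74 without WT vehicle 1, 86 and 87 without Mas-/- vehicle 1 and 2, 112 without Mas-/- agonist 2 or WT agonist 1 and 134 without WT agonist 3. Between genotypes on the agonist (281) it was 1775 with array weights, 49 with the range covariate, 437 with only the groups compared, and, added later, 501 with a heart muscle covariate, 37 with heart muscle, fat and airway covariates, 135 without chromosomes 4 and 17 and 63 with animal numbers starting with 88 alone. Leaving out a library gave 49 (WT agonist 3) to 424 (Mas-/- vehicle 3), with 57 and 62 without Mas-/- agonist 1 and 2, 93 without WT agonist 1 and 176 without WT vehicle 1. Dropping chromosomes 4 and 17 also changes the adjustment, so 30 and 135 are not the numbers of calls that lie outside them. Of the 205 and 281 calls, 122 and 197 lay outside the stretches of these chromosomes. Averaged over treatments (693) the count was 2021 with array weights, 33 with the range covariate, and, added later, 1192 with the heart muscle covariate and 269 with all 3 covariates. Leaving out a library gave 422 (Mas-/- agonist 1) to 1123 (Mas-/- vehicle 3), with 435 without WT agonist 3 and 438 without Mas-/- agonist 2. The share of calls that were higher was 27.8%, 19.9% and 24.2% in these comparisons, and 38.6%, 42.2% and 45.0% with array weights and 54.5%, 36.7% and 39.4% with the range covariate. The agonist in WT mice gave 12 calls with array weights and 0 to 1 on leaving out a library (1 without Mas-/- vehicle 2 or WT agonist 3), in labelled Mas-/- mice 0 to 2 (2 without Mas-/- vehicle 2), for the difference 0 to 1 (1 without Mas-/- vehicle 2 or WT agonist 3), and averaged 1 with array weights and 0 to 2 (2 without Mas-/- vehicle 2, 1 without WT agonist 3). With an estimated correlation 0 lists passed in every comparison, and with fry 0 except 1 for genotype averaged over treatments. Lists passing with camera on leaving out a library ranged from 17 to 23 (genotype on vehicle), 16 to 26 (agonist in WT, 16 without WT vehicle 1), 6 to 17 (agonist in labelled Mas-/-, 17 without Mas-/- vehicle 2, 15 and 13 without Mas-/- agonist 1 and 3), 10 to 22 (difference, 10 without WT vehicle 1), 12 to 17 (genotype on the agonist), 13 to 18 (genotype averaged) and 14 to 22 (agonist averaged). Of 72 named calls 32 were kept in every setting.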

Other observations

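Some single genes called lower under the Mas-/- label in the average have not been described. The NADPH oxidase genes Cybb (log2 fold change -0.53 ± 0.11, limma adjusted p = 0.0116) and Ncf1 (-0.64 ± 0.12, adjusted p = 0.00883) fell. In the same average neutrophil genes had a median of -1.65 and monocyte and interstitial macrophage genes -0.29. Whether Cybb and Ncf1 fell apart from these cell types was not tested. Edn1, which encodes the vasoconstrictor endothelin 1, fell by 0.59 on the log2 scale (SE 0.14, limma adjusted p = 0.0395), and Bmp6 fell by 0.46 (SE 0.07), while the BMP and TGF-beta list did not pass (limma camera adjusted p = 0.570).

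Nnt, a mitochondrial transhydrogenase gene that carries a deletion in some C57BL/6 substrains, read 19.1 ± 2.05 CPM in WT and 39.6 ± 11.2 CPM in labelled Mas-/- libraries (n = 6 each, exact permutation p = 0.00216, the smallest it can give). Nlrp12, which also varies among substrains, read 22.5 ± 8.67 and 7.62 ± 3.24 CPM (exact permutation p = 0.00433), while Wdfy1, Crb1 and Cyfip2 had exact permutation p = 0.0823, 0.214 and 0.167. These genes were chosen after the data were seen, and Nlrp12 is also a gene of neutrophils.

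List scores per library were also compared by exact permutation within the other factor, a test added after the lists had been seen. Between genotypes 10 of 44 lists passed unadjusted and 0 adjusted, with neutrophil and platelet scores at exact permutation p = 0.005, the smallest it can give, and adjusted p = 0.088. For the agonist 2 passed unadjusted and 0 adjusted, with mesothelial genes at exact permutation p = 0.015, and for the difference 1 and 0, with erythroid genes at exact permutation p = 0.02.

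A hypothesis is that part of the genotype effect may come from DNA of another background rather than from loss of Mas, linked to Mas1 on chromosome 17 and unlinked on chromosome 4, since 28 genes were called in a 5 Mb window of each chromosome, with 16 as the highest count in permutations. Calling variants from the reads, or comparing littermates from heterozygous parents, would test it. A further hypothesis is that lungs labelled Mas-/- could hold fewer neutrophils, as the neutrophil median stayed at -1.42 among agonist mice with numbers starting with 88. The numbers of these mice still do not overlap between labels. Counting neutrophils by flow cytometry in lungs of littermates, with Mas1 genotyped again, would test this hypothesis.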
